A study of Mus musculus with 18 samples.

How the data were processed

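Gene expression was measured by hybridisation of labelled RNA to Affymetrix mouse Gene 1.0 ST arrays, with 18 arrays in 6 groups of 3 from cells of CD1 mice. The groups were neonatal cardiomyocytes (CM), neonatal cardiac fibroblasts (CF), and GFP+ induced cardiomyocyte-like cells (iCMs) and GFP- cells in which reprogramming failed, both at 2 weeks and at 4 weeks. Per the labels, RNA was isolated with the PicoPure kit and labelled with the MessageAmp II-biotin kit. The deposited values are log2 intensities per probe set that the authors made with RMA (background correction, normalization across arrays and a summary per probe set), whose version and software are not given in the labels. All 18 columns were mapped to a sample, 0 columns were left over, no value was missing and no columns were identical. The values ran on a log2 scale with medians per array from 7.32 to 7.44. On arrays the number of arrays limits the precision, and the signal of a probe set that lies near background cannot show a fall. Values close to the highest of each array (13.82 to 13.95) can hide a difference in the same way.

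The table held 28682 probe sets, of which 21755 named 1 gene, 1592 named several and 5335 had no gene name. Where several probe sets named 1 gene (997 genes), the probe set with the highest mean over all 18 arrays was used, which gave 19912 genes. Probe sets that named no gene or several genes were left out of the comparisons.

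One linear model per gene was fitted to all 18 arrays with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with group as the only term. The prior had 6.96 degrees of freedom and an SD of 0.131 log2, beside 12 residual degrees of freedom. From it 12 comparisons were drawn, 11 between pairs of groups and 1 interaction (the change of GFP+ cells from 2 to 4 weeks minus that of GFP- cells). P-values were adjusted by the Benjamini-Hochberg method over all genes within each comparison, and a gene was called at an adjusted p under 0.05. Errors of differences are standard errors (SE) from limma, errors of group means are standard deviations (SD), and n = 3 arrays in every group. All limma tests were two-sided.

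Before the data were examined, 24 gene lists (405 genes, 379 measured, 11 of the measured genes in more than 1 list), the comparisons, the other settings and the rule for named genes were fixed. The lists covered reprogramming factors used in the field (Gata4, Mef2c and Tbx5), the sarcomere and contractile apparatus, calcium handling and ion channels, other cardiac transcription factors, muscle energy metabolism, atrial-enriched and ventricular-enriched genes, fibroblast and extracellular matrix genes, smooth muscle and myofibroblast genes, and skeletal muscle. They also covered markers of endothelial cells, macrophages and leukocytes, epicardium and mesothelium, Schwann cells and neural crest glia, erythroid cells, adipocytes, bone and cartilage, mesoderm and cardiac progenitors, and pluripotency. The remaining lists were proliferation, cell cycle inhibitors and p53 targets, the interferon response, inflammatory cytokines and acute phase genes, and immediate early and dissociation stress genes. Named genes are the 6 largest rises and the 6 largest falls among called genes whose arrays do not overlap between the groups (which chance gives in 10% of genes at 3 against 3), up to 4 members per list with the largest changes, and 23 anchor genes, leaving out predicted and unnamed genes. Genes named outside this rule are identified as such.

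Each list was tested against the other genes with camera at a preset correlation of 0.01, with an estimated correlation as an alternative, and with fry, which tests whether the genes of a list move one way on balance. P-values were adjusted over the 288 tests of 24 lists in 12 comparisons. Camera passed 149 of them, and 70 of those passed with an estimated correlation. Members were also counted with p-values adjusted over the list alone.

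Position on the axis from fibroblast to cardiomyocyte was, per array, the median over genes of the distance from the CF mean, as a percentage of the distance between the CF and CM means. It used genes called between CM and CF with at least a 4-fold difference, 298 higher in cardiomyocytes and 448 higher in fibroblasts, and groups were compared with two-sided exact permutation tests, whose smallest p at 3 against 3 is 0.1. Positions of gene lists, added after the data had been seen, used members called between CM and CF with at least a 2-fold difference. Overlap between the calls of GFP+ against GFP- cells at 2 and at 4 weeks was set against the number that independent calls would give.

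The alternatives tried were quantile and cyclic loess normalization of the deposited values, array weights, an intensity trend, a fit of only the groups compared, a minimum fold of 2, leaving out genes under the 25th percentile of mean signal, all probe sets in place of 1 per gene, the replicate number as a block, other axis settings, and leaving out each replicate in turn. The spread of each array's values as a covariate was added after the data had been seen. The labels do not say that a replicate number is a shared preparation. In 0 of 15 pairs of groups did arrays with the same number all correlate above 0.1 after group means were removed. The block was thus only an alternative. The pipeline was tested on simulated 2-week GFP+ cells against fibroblasts, with 200 changed genes and independent noise per gene. It recovered 67.8% and 99.7% of genes changed by 0.5 and 1 log2. Of the calls 6.21% were false, and an unchanged comparison gave 1 call in 10 runs. Real arrays shared deviations between genes, and more genes differed, so these rates need not hold there. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.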

Results

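The data describe how far cells reprogrammed from fibroblasts towards cardiomyocytes had moved, over time, from the one cell type to the other. Neonatal cardiomyocytes (CM) and cardiac fibroblasts (CF) gave the reference profiles. GFP+ induced cardiomyocyte-like cells (iCMs) and GFP- cells in which reprogramming failed were profiled at 2 and 4 weeks, with 3 arrays per group. The labels name neither the factors used for reprogramming nor the promoter that drives GFP. Median log2 values per array ran from 7.32 to 7.44, and the number of arrays limits the precision. Group means under 6.16 log2, the lowest 25th percentile of any array, were taken as not above background, a limit set after the data had been seen. Differences between groups that rest on such a mean are lower bounds, among them those of Bex1, Smpx, Aspn and Emcn against fibroblasts and of Msr1, Fcrls, Ms4a7, Wfdc17, Adgre1 and Saa3 against cardiomyocytes. In single comparisons this also holds for Myoz2, Rgs5, Enpep, Ppp1r3c, Dpt, Plac8, Clec4e, Clec5a, Ifitm6, Kcnj2, Lum, Rgs7, Vsig4, Cd209f and Tmem92. Arrays of 1 group correlated with each other at r = 0.990 to 0.996 across genes. The principal components that carried the most variance (56% and 22.7%) set the 3 cardiomyocyte arrays, the 6 GFP+ arrays, and the 9 fibroblast and GFP- arrays apart. The design text calls the arrays of a group biological replicates, and the labels do not say whether they come from separate cultures, so p-values measure the spread between these arrays.

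Cardiomyocytes were compared with cardiac fibroblasts to define the end points. Actc1, the cardiac alpha-actin, was at least 89-fold higher in cardiomyocytes (13.61 ± 0.06 against 7.14 ± 0.29 log2, mean ± SD, n = 3). Myh6, the alpha-myosin heavy chain, and Pln, phospholamban, were both at least 82.3-fold higher. Bex1 stood at 11.11 ± 0.13 log2 in cardiomyocytes against 4.06 ± 0.07 in fibroblasts. The muscle protein Smpx (at least 6.74 ± 0.21 log2, SE) and the Z-disc protein Myoz2 (at least 6.46 ± 0.10) were higher too. On the fibroblast side, the largest differences were in genes of macrophages, among them Msr1, a scavenger receptor (at least 99.8-fold, 12.33 ± 0.09 in fibroblasts against 5.68 ± 0.33 log2), and Fcrls (-6.74 ± 0.16). Others were Lyz2, a lysozyme (-6.46 ± 0.10), Adgre1, the F4/80 antigen (-6.34 ± 0.21), Wfdc17 (-6.49 ± 0.17) and Ms4a7 (-6.36 ± 0.25).

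Of the sarcomere genes, 32 of 32 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 1.1e-32), with a median log2 difference of 4.83. In calcium handling and ion channels 25 of 29 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 1.13e-17), including Ryr2, the calcium release channel (5.58 ± 0.10), and the calcium-binding Casq2 (5.44 ± 0.28). In muscle energy metabolism 30 of 31 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 1.69e-28), led by the cytochrome oxidase subunit Cox8b (6.30 ± 0.16) and Ppargc1a, a coactivator of mitochondrial genes (6 ± 0.21). Among other cardiac transcription factors 14 of 16 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 1.04e-08), with Prox1 at 3.71 ± 0.10, and Nkx2-5 differed by 0.42 ± 0.11. With so small a difference between the end points, the probe set of Nkx2-5 can show little of a move between them. For atrial-enriched genes 8 of 9 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 7.33e-09), with Nppa at 6.34 ± 0.21. For ventricular-enriched genes 6 of 6 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 8.02e-10), with Myl2 at 6.33 ± 0.08. Of the 3 reprogramming factors 2 of 3 were higher and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 0.124), with Tbx5 at 2.64 ± 0.11, Gata4 at 0.97 ± 0.13 and Mef2c at -0.41 ± 0.13. The call of Mef2c was lost without replicate 3 of the cardiomyocytes (adjusted p = 0.0705), without replicate 3 of the fibroblasts (0.0665) and with the spread of each array as a covariate (0.0603).

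Of the fibroblast and extracellular matrix genes, 4 of 33 were higher and 22 lower (the same counts adjusted over the list alone, camera adjusted p = 1.13e-06, adjusted p = 0.238 with an estimated correlation). Fibronectin (Fn1) differed by -2.51 ± 0.15 and the collagen Col3a1 by -1.57 ± 0.10, while Postn, periostin, did not pass the test (0.65 ± 0.30, adjusted p = 0.0907). Postn stood at 12.16 ± 0.13 against 11.51 ± 0.12 log2 (SD) and was called higher in cardiomyocytes with cyclic loess (adjusted p = 0.0431), with the spread covariate (0.00173) and when only these groups were fitted (0.000255). Of the macrophage markers, 0 of 24 were higher and 22 lower (the same counts adjusted over the list alone, camera adjusted p = 1.31e-25), and their mean over the list was 10.99 ± 0.09 log2 (SD, n = 3) in the fibroblast arrays and 6.69 ± 0.11 in the cardiomyocyte arrays. Inflammatory and acute phase genes went the same way: 0 of 16 were higher and 14 lower (the same counts adjusted over the list alone, camera adjusted p = 1.92e-11), with Saa3 at -6.08 ± 0.20 and Ccl3 at -5.23 ± 0.11. For the interferon response 0 of 18 were higher and 15 lower (1 and 16 adjusted over the list alone, camera adjusted p = 7.35e-06, adjusted p = 0.228 with an estimated correlation). For immediate early genes 0 of 13 were higher and 9 lower (the same counts adjusted over the list alone, camera adjusted p = 0.00107, adjusted p = 0.237 with an estimated correlation). Endothelial markers were higher on the cardiomyocyte side: 15 of 18 were higher and 2 lower (the same counts adjusted over the list alone, camera adjusted p = 1.86e-06), with Cdh5, the VE-cadherin, at 3.71 ± 0.12. Of skeletal muscle genes 10 of 23 were higher and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0141, adjusted p = 0.192 with an estimated correlation). Of epicardial and mesothelial genes 1 of 13 were higher and 9 lower (2 and 10 adjusted over the list alone, camera adjusted p = 0.00815, adjusted p = 0.321 with an estimated correlation). Of cell cycle inhibitors and p53 targets 1 of 11 were higher and 7 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0219, adjusted p = 0.353 with an estimated correlation). Of smooth muscle and myofibroblast genes 6 of 15 were higher and 7 lower (6 and 9 adjusted over the list alone, camera adjusted p = 0.588), with Tagln at -3.08 ± 0.24 and Rgs5 at 3.04 ± 0.16. Proliferation genes gave no call as a list: 7 of 25 were higher and 3 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.231). Over all genes, 8169 of 19912 were called, 3894 higher and 4275 lower in cardiomyocytes, and 2348 of them differed at least 2-fold.

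GFP+ cells at 2 weeks were compared with cardiac fibroblasts to measure how far they lay from the fibroblast profile. Actc1 was 63.3-fold higher in the GFP+ cells (13.12 ± 0.14 against 7.14 ± 0.29 log2, SD, n = 3), and Myl7, the atrial myosin light chain, 51.1-fold. Nppa, the atrial natriuretic peptide, was higher by 5.66 ± 0.21 log2 (SE), desmoplakin (Dsp) by 5.50 ± 0.10, and Smpx by at least 5.43 ± 0.21. Bex1 stood at 9.80 ± 0.19 log2 (SD). Lower in GFP+ cells were the matrix genes Dpt (-5.26 ± 0.19) and Aspn (-3.52 ± 0.14), the matrix protease Mmp3 (-4.34 ± 0.18), Plac8 (-4.98 ± 0.22), F13a1 (-3.54 ± 0.20) and Rasgrp3 (-3.49 ± 0.10). Tbx5, Gata4 and Mef2c were higher by 4.91 ± 0.11, 2.07 ± 0.13 and 1.09 ± 0.13. As a list, 3 of 3 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 2.06e-05), and the labels do not say whether introduced copies are included.

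Of the sarcomere genes, 28 of 32 were higher and 1 lower (29 and 1 adjusted over the list alone, camera adjusted p = 1.64e-24). Myh6 was 15.4-fold and Tnnt2, cardiac troponin T, 7.18-fold higher, whereas Myl2, the ventricular light chain, stayed near background (-0.55 ± 0.08). In calcium handling and ion channels 20 of 29 were higher and 2 lower (21 and 2 adjusted over the list alone, camera adjusted p = 3.49e-07), with Casq2 (5.02 ± 0.28) and Ryr2 (4.60 ± 0.10) higher and the potassium channel Kcnj2 lower (-2.27 ± 0.13). In muscle energy metabolism 20 of 31 were higher and 1 lower (21 and 1 adjusted over the list alone, camera adjusted p = 3.58e-08), with the muscle enzymes Pgam2 (4.18 ± 0.13) and Eno3 (3.61 ± 0.11). Atrial-enriched genes gave 7 higher and 1 lower of 9 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00013), ventricular-enriched genes 2 and 1 of 6 (3 and 1 adjusted over the list alone, camera adjusted p = 0.512). Among other cardiac transcription factors 6 of 16 were higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.216), with Tbx20 at 0.78 ± 0.15, and Nkx2-5 was at -0.12 ± 0.11 (adjusted p = 0.451). Without replicate 1 of the 2-week GFP+ cells Nkx2-5 was called lower (-0.28, adjusted p = 0.0219). Its probe set separated cardiomyocytes from fibroblasts only weakly, so these values do not show whether Nkx2-5 was induced.

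Fibroblast and matrix genes were mostly lower at 2 weeks: 3 of 33 were higher and 24 lower (3 and 26 adjusted over the list alone, camera adjusted p = 2.47e-11, adjusted p = 0.108 with an estimated correlation). Postn was lower by 9.51-fold and Col3a1 by 4.67-fold, while Thy1, a surface antigen of fibroblasts, was 4.21-fold higher (2.07 ± 0.21). Of the macrophage markers 0 of 24 were higher and 22 lower (1 and 22 adjusted over the list alone, camera adjusted p = 1.43e-22), with Adgre1 at -2.77 ± 0.21 and the leukocyte antigen Ptprc at -2.58 ± 0.13. Inflammatory genes were lower beside them: 1 of 16 were higher and 10 lower (the same counts adjusted over the list alone, camera adjusted p = 4.11e-05), with Il1b at -2.24 ± 0.20 and Il6 at -2.07 ± 0.19. Proliferation genes were lower: 1 of 25 were higher and 23 lower (1 and 24 adjusted over the list alone, camera adjusted p = 6.77e-13, adjusted p = 0.105 with an estimated correlation), with Mki67, a marker of cycling cells, at -1.73 ± 0.16 and the spindle checkpoint kinase Bub1 at -2.07 ± 0.19. Mesothelial genes were higher: 8 of 13 were higher and 2 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0166, adjusted p = 0.377 with an estimated correlation), with mesothelin (Msln) at 3.44 ± 0.17 and the uroplakin Upk1b at 2.52 ± 0.25. Skeletal muscle genes gave 6 higher of 23 (6 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.186 with an estimated correlation), led by the fast troponin Tnnt3 (2.64 ± 0.12). In total 6622 genes were called, 3467 higher and 3155 lower, and of the 1440 that differed at least 2-fold, 602 were higher and 838 lower.

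At 4 weeks the GFP+ cells were compared with the same fibroblast arrays. Actc1 was 73.3-fold (13.33 ± 0.06 log2, SD, n = 3), Myl7 68-fold and Myh6 39.2-fold higher. Enpep, glutamyl aminopeptidase, was higher by 5.76 ± 0.21 log2 (SE), Ppp1r3c, a subunit that targets a phosphatase to glycogen, by 5.63 ± 0.13, Smpx by 5.83 ± 0.21 and Dsp by 5.49 ± 0.10. Dpt was 70.8-fold and Postn 22.6-fold lower. The other large falls against fibroblasts were Plac8 (-5.32 ± 0.22), the macrophage lectin Clec4e (-4.83 ± 0.17), the chemokine Ccl12 (-4.47 ± 0.14) and Ifitm6 (-4.39 ± 0.18).

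Of sarcomere genes 30 of 32 were higher and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 1.71e-30), with Actn2, the Z-disc alpha-actinin, 9.16-fold higher and Myl2 near background (-0.32 ± 0.08). In calcium handling and ion channels 19 of 29 were higher and 2 lower (21 and 2 adjusted over the list alone, camera adjusted p = 3.06e-11), with Ryr2 at 5.03 ± 0.10, Pln at 3.48 ± 0.25 and sarcolipin (Sln) at 3.25 ± 0.26. In muscle energy metabolism 24 of 31 were higher and 0 lower (25 and 0 adjusted over the list alone, camera adjusted p = 2.14e-14), with Pgam2 at 4.93 ± 0.13. For atrial-enriched genes 6 of 9 were higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 2.36e-05). Ventricular-enriched genes gave no call as a list: 2 of 6 were higher and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 0.225). Of the reprogramming factors 3 of 3 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 1.52e-05). Of other cardiac transcription factors 7 of 16 were higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.04, adjusted p = 0.168 with an estimated correlation), with Prox1 at 1.56 ± 0.10 and Nkx2-5 at 0.14 ± 0.11 (adjusted p = 0.4). The weak separation of the end points by the Nkx2-5 probe set limits its value at 4 weeks too. For skeletal muscle genes 9 of 23 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 0.00101, adjusted p = 0.0889 with an estimated correlation), with Tnnt3 at 3.80 ± 0.12 and the fast light chain Myl1 at 1.96 ± 0.20.

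Of the matrix genes 1 of 33 were higher and 26 lower (1 and 27 adjusted over the list alone, camera adjusted p = 1.98e-18), with the growth factor receptor Pdgfra at -3.18 ± 0.12. Macrophage markers stayed below the fibroblast level: 0 of 24 were higher and 21 lower (0 and 22 adjusted over the list alone, camera adjusted p = 2.44e-26), with the receptor Csf1r at -3.10 ± 0.13. Inflammatory genes moved with them: 1 of 16 were higher and 13 lower (the same counts adjusted over the list alone, camera adjusted p = 1.43e-09). Of proliferation genes 1 of 25 were higher and 24 lower (the same counts adjusted over the list alone, camera adjusted p = 2.56e-19), with Mki67 6.48-fold lower. Immediate early genes gave 2 higher and 7 lower of 13 (2 and 8 adjusted over the list alone, camera adjusted p = 0.0354, adjusted p = 0.477 with an estimated correlation). The lists of Schwann, erythroid, adipocyte, bone, mesoderm and pluripotency genes gave no call with camera. For Schwann and glial genes 0 of 6 were higher and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 0.925). For erythroid genes 0 of 3 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 0.929). For adipocyte genes 1 of 9 were higher and 2 lower (the same counts adjusted over the list alone, camera adjusted p = 0.725). For bone and cartilage 0 of 8 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 0.875). For mesoderm and cardiac progenitor genes 0 of 9 were higher and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 0.787). For pluripotency genes 0 of 9 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 0.793). In all, 5878 genes were called, 2852 higher and 3026 lower, 1541 of them at least 2-fold.

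**Figure D1:**
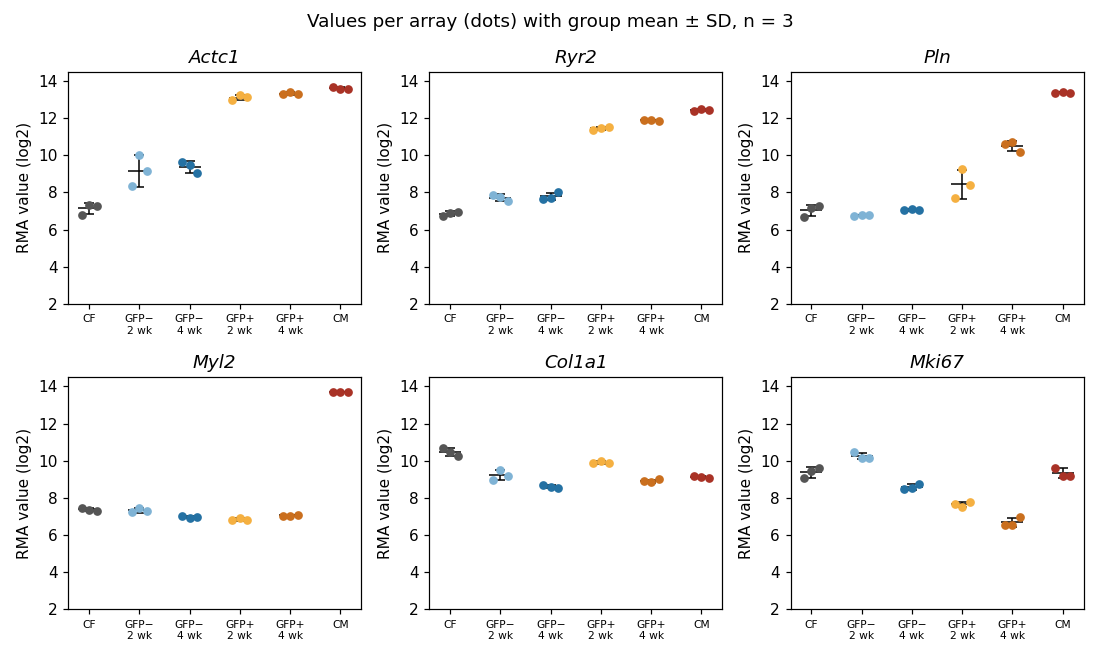
Log2 RMA values of 6 genes (y axis) in the 6 groups of arrays (x axis), where dots are arrays and bars are the group mean ± SD (n = 3). Actc1 and Ryr2 lay near the cardiomyocyte level in GFP+ cells, Pln rose from 8.45 to 10.51 between 2 and 4 weeks, Myl2 stayed near the fibroblast level, and Mki67 was lowest in GFP+ cells.

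GFP+ and GFP- cells at 2 weeks were compared to separate the cells that switched on the reporter from those that did not. Casq2 was 20.6-fold higher in GFP+ cells (11.93 ± 0.46 against 7.57 ± 0.88 log2, SD, n = 3), titin (Ttn) 16.2-fold, Actc1 15.5-fold and Enpep 18.2-fold. Myoz2 (4.11 ± 0.10 SE) and Smpx (3.97 ± 0.21) also stood among the largest rises. The largest falls were the Toll-like receptors Tlr7 (-3.15 ± 0.17) and Tlr8 (-3.12 ± 0.18), Ms4a6b (-3.23 ± 0.22), Stap1 (-3.17 ± 0.13), Ifitm6 (-3.15 ± 0.18) and the fatty acid transporter Cd36 (-3.11 ± 0.16). Tbx5 (2.36 ± 0.11), Gata4 (1.71 ± 0.13) and Mef2c (0.77 ± 0.13) were higher in GFP+ cells. As a list, 3 of 3 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 0.000306).

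Sarcomere genes gave the clearest rise: 28 of 32 were higher and 1 lower (29 and 1 adjusted over the list alone, camera adjusted p = 3.62e-23), with Myh6 at 3.75 ± 0.21 and Tnnt2 at 1.36 ± 0.16. In calcium handling and ion channels 18 of 29 were higher and 3 lower (19 and 3 adjusted over the list alone, camera adjusted p = 8.92e-07), with Ryr2 at 3.75 ± 0.10. In energy metabolism 16 of 31 were higher and 4 lower (18 and 4 adjusted over the list alone, camera adjusted p = 0.000181, adjusted p = 0.119 with an estimated correlation). Among other cardiac transcription factors 8 of 16 were higher and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 0.00657, adjusted p = 0.0746 with an estimated correlation), with Tbx20 at 2.41 ± 0.15. Smooth muscle and myofibroblast genes were higher in GFP+ cells: 10 of 15 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 6.3e-06, adjusted p = 0.136 with an estimated correlation), with Acta2, the smooth muscle actin, at 1.78 ± 0.23. In log2, Acta2 stood at 12.27 in GFP+ cells, 12.21 in fibroblasts and 10.49 in GFP- cells, and Tagln at 10.65, 10.73 and 8.87. For these genes the contrast rested on lower values in GFP- cells. Myl9 (12.13, 10.93 and 9.47) also lay above fibroblasts in GFP+ cells. Mesothelial genes were higher: 9 of 13 were higher and 0 lower (10 and 0 adjusted over the list alone, camera adjusted p = 1.88e-05, adjusted p = 0.11 with an estimated correlation). Matrix genes did not move as a list: 14 of 33 were higher and 5 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0644), with Thy1 (2.37 ± 0.21) and Ddr2 (1.40 ± 0.16) higher and lumican (Lum, -1.25 ± 0.17) lower. Macrophage markers were lower in GFP+ cells: 0 of 24 were higher and 22 lower (the same counts adjusted over the list alone, camera adjusted p = 4.83e-21). Inflammatory genes were lower beside them: 0 of 16 were higher and 12 lower (the same counts adjusted over the list alone, camera adjusted p = 3.55e-06). For the interferon response 0 of 18 were higher and 9 lower (the same counts adjusted over the list alone, camera adjusted p = 0.018, adjusted p = 0.589 with an estimated correlation). For endothelial markers 2 of 18 were higher and 10 lower (2 and 11 adjusted over the list alone, camera adjusted p = 0.0129, adjusted p = 0.253 with an estimated correlation). For proliferation 1 of 25 were higher and 24 lower (the same counts adjusted over the list alone, camera adjusted p = 1.98e-18, adjusted p = 0.0509 with an estimated correlation), with Mki67 at -2.61 ± 0.16. In total 6874 genes were called, 3218 higher and 3656 lower.

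The same comparison at 4 weeks gave 27.9-fold more Myh6 in GFP+ cells (12 ± 0.10 against 7.19 ± 0.07 log2, SD, n = 3), 25.1-fold more Ttn and 11-fold more Pln. Enpep (5.08 ± 0.21 SE), Casq2 (4.57 ± 0.28), Smpx (4.45 ± 0.21) and Jph1, which joins the plasma membrane to the sarcoplasmic reticulum (4.41 ± 0.29), were among the largest rises. The largest falls at 4 weeks were the Toll-like receptors Tlr13 (-3.81 ± 0.19), Tlr8 (-3.70 ± 0.18) and Tlr7 (-3.69 ± 0.17), the cytokine receptor Il7r (-3.70 ± 0.21), Stap1 (-3.69 ± 0.13) and Cd200r1 (-3.69 ± 0.14).

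Sarcomere genes were higher again: 30 of 32 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 2.95e-27). In calcium handling 18 of 29 were higher and 2 lower (the same counts adjusted over the list alone, camera adjusted p = 5.87e-09). In energy metabolism 22 of 31 were higher and 2 lower (the same counts adjusted over the list alone, camera adjusted p = 5.94e-09), where Cd36 was lower (-3.57 ± 0.16). For skeletal muscle 9 of 23 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 0.000361, adjusted p = 0.0673 with an estimated correlation), with Tnnt3 at 3.91 ± 0.12. For smooth muscle and myofibroblast genes 11 of 15 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 5.78e-05, adjusted p = 0.191 with an estimated correlation), with Myl9 at 3.13 ± 0.21. Myl9 (12.28 log2 in GFP+ cells, 10.93 in fibroblasts and 9.15 in GFP- cells) was above fibroblasts in GFP+ cells and below them in GFP- cells. Acta2 (12.51, 12.21 and 10.27) and Tagln (10.91, 10.73 and 9.23) differed mainly by their lower values in GFP- cells. The matrix list was lower on balance: 4 of 33 were higher and 12 lower (5 and 12 adjusted over the list alone, camera adjusted p = 0.0345, adjusted p = 0.673 with an estimated correlation), with Lum at -3.34 ± 0.17 and Fn1 at -1.29 ± 0.15, but Thy1 was higher (1.89 ± 0.21). Macrophage markers were lower: 0 of 24 were higher and 22 lower (the same counts adjusted over the list alone, camera adjusted p = 1.1e-25), with Laptm5 at -3.14 ± 0.09. Beside them, inflammatory genes were lower: 0 of 16 were higher and 15 lower (the same counts adjusted over the list alone, camera adjusted p = 1.14e-13). In the interferon response 1 of 18 were higher and 14 lower (1 and 16 adjusted over the list alone, camera adjusted p = 1.83e-06, adjusted p = 0.197 with an estimated correlation). Endothelial markers were lower too: 1 of 18 were higher and 10 lower (1 and 12 adjusted over the list alone, camera adjusted p = 5.29e-05, adjusted p = 0.072 with an estimated correlation), with endomucin (Emcn) at -3.51 ± 0.16. Of proliferation genes 1 of 25 were higher and 23 lower (the same counts adjusted over the list alone, camera adjusted p = 3.73e-12, adjusted p = 0.114 with an estimated correlation). In total 6816 genes were called, 3421 higher and 3395 lower, and 684 were higher and 1019 lower at least 2-fold. Of the genes higher in GFP+ cells, 2385 were called at both times, against 553 if the calls were independent, and 33 were called in opposite directions. For lower genes 2656 were shared, against 623, with 20 opposite.

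Within GFP+ cells, the largest rises from 2 to 4 weeks included muscle genes. Nebl, the Z-disc protein nebulette, rose 5.09-fold (from 6.96 ± 0.16 to 9.30 ± 0.14 log2, SD, n = 3), Pln 4.17-fold and Ppp1r3a, the muscle glycogen-targeting subunit, 4.16-fold. Vsnl1 (2.23 ± 0.22 SE), Rgs7 (1.98 ± 0.17), Ppargc1a (1.69 ± 0.21), Myh6 (1.35 ± 0.21) and Actn2 (1.15 ± 0.12) also rose. Clec4e (-2.20 ± 0.17), Clec5a (-1.59 ± 0.14), Sla (-1.51 ± 0.15) and Ifitm6 (-1.84 ± 0.18), genes expressed in leukocytes, fell, as did the collagen-linking enzyme Lox (-1.71 ± 0.29) and the small nucleolar RNA gene Rnu3a (-1.60 ± 0.30). Col1a1 fell by 1.00 ± 0.12 and Nppa by 0.96 ± 0.21, whereas Actc1 (0.21 ± 0.26, adjusted p = 0.698) and Gata4 (-0.10 ± 0.13, adjusted p = 0.709) did not pass the test. Actc1 lay close to the top of the scale at both times.

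Of the sarcomere genes 8 of 32 rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 1.68e-06, adjusted p = 0.118 with an estimated correlation). In calcium handling and ion channels 10 of 29 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 1.38e-07), with Hrc at 1.44 ± 0.21 and the potassium channel Kcnj3 at 1.18 ± 0.22. In energy metabolism 9 of 31 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 4.06e-08), with Cox8b at 1.11 ± 0.16. Matrix genes fell in most called cases: 1 of 33 rose and 18 fell (1 and 23 adjusted over the list alone, camera adjusted p = 1.51e-10, adjusted p = 0.118 with an estimated correlation), with Bgn at -1.09 ± 0.18, while Lum rose (1.22 ± 0.17). Of the macrophage markers 0 of 24 rose and 13 fell (0 and 17 adjusted over the list alone, camera adjusted p = 5.16e-11), with Cd14 at -1.34 ± 0.15. Of inflammatory genes 0 of 16 rose and 9 fell (1 and 9 adjusted over the list alone, camera adjusted p = 5.51e-06), with Ccl2 at -1.28 ± 0.13. Proliferation genes fell further: 0 of 25 rose and 15 fell (0 and 18 adjusted over the list alone, camera adjusted p = 1.89e-13, adjusted p = 0.0974 with an estimated correlation). Of immediate early genes 0 of 13 rose and 2 fell (the same counts adjusted over the list alone, camera adjusted p = 0.0121, adjusted p = 0.375 with an estimated correlation). Of skeletal muscle genes 4 of 23 rose and 1 fell (the same counts adjusted over the list alone, camera adjusted p = 0.0466, adjusted p = 0.293 with an estimated correlation). Of mesothelial genes 0 of 13 rose and 3 fell (0 and 5 adjusted over the list alone, camera adjusted p = 0.0361, adjusted p = 0.457 with an estimated correlation). Of cell cycle inhibitors and p53 targets 1 of 11 rose and 4 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.025, adjusted p = 0.365 with an estimated correlation). In total 2297 genes were called, 855 higher and 1442 lower at 4 weeks, and 101 changed at least 2-fold. The lean to falls depended on the scaling, with 37.2% of the called genes higher here, 45.9% (1346 higher, 1588 lower) with quantile normalization and 48.3% (1750 and 1876) with the spread covariate. The count was 1421 without replicate 3 of the 2-week GFP+ cells, 1289 without replicate 2 of the 4-week GFP+ cells, and 1486 when only these groups were fitted. It rose to 5985 with array weights and to 3626 with the spread of each array as a covariate, an alternative chosen after the data had been seen.

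GFP+ cells were then compared with cardiomyocytes to measure what still set them apart. The cardiomyocyte arrays also held matrix and endothelial transcripts, with Dpt at 11.79, Postn at 12.16 and Cdh5 at 10.48 log2. Fibroblasts held Dpt at 11.86 and Postn at 11.51. Lower values of such genes in GFP+ cells are differences from these arrays and are not shown to concern the cardiomyocytes themselves. At 2 weeks Myl2 was 117-fold lower in GFP+ cells (6.83 ± 0.05 against 13.70 ± 0.02 log2, SD, n = 3), and the ventricular light chain Myl3 71.4-fold. Cox8b (-5.84 ± 0.16 SE), Nebl (-5.24 ± 0.11), Pln (-4.94 ± 0.25) and the matrix genes Aspn (-6.26 ± 0.14) and Dpt (-5.19 ± 0.19) were lower as well. Higher than in cardiomyocytes were the acute phase gene Saa3 (77.7-fold), Lyz2 (5.44 ± 0.10), Anxa8 (5.36 ± 0.16), Upk1b (5.24 ± 0.25), Scg2 (5.17 ± 0.22) and Tspan8 (5.02 ± 0.25). Tnnt2 (-0.11 ± 0.16, adjusted p = 0.641), Actc1 (-0.49 ± 0.26, adjusted p = 0.153) and Myl7 (-0.34 ± 0.16, adjusted p = 0.106) did not pass the test. Actc1 was called lower when only these groups were fitted (adjusted p = 0.00259) and with the spread covariate (0.0458). Myl7 was called lower with both of these (0.029 and 0.0293), with quantile normalization (0.0361) and with cyclic loess (0.0287). Tnnt2 (13.73 ± 0.04 against 13.84 ± 0.02 log2, SD) and Actc1 (13.12 ± 0.14 against 13.61 ± 0.06) lay close to the highest values of the arrays (13.82 to 13.95), where a difference can be hidden.

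Sarcomere genes remained lower at 2 weeks: 1 of 32 were higher and 22 lower (2 and 22 adjusted over the list alone, camera adjusted p = 7.36e-13). In energy metabolism 0 of 31 were higher and 30 lower (the same counts adjusted over the list alone, camera adjusted p = 5.02e-25). In calcium handling 1 of 29 were higher and 21 lower (1 and 22 adjusted over the list alone, camera adjusted p = 6.59e-12). Among other cardiac transcription factors 0 of 16 were higher and 13 lower (the same counts adjusted over the list alone, camera adjusted p = 1.04e-08), with Hopx at -3.27 ± 0.18. For ventricular-enriched genes 0 of 6 were higher and 6 lower (the same counts adjusted over the list alone, camera adjusted p = 2.19e-10). For atrial-enriched genes 0 of 9 were higher and 6 lower (the same counts adjusted over the list alone, camera adjusted p = 0.000641). The reprogramming factors were above the cardiomyocyte level: 3 of 3 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 0.00148), with Mef2c at 1.51 ± 0.13. Macrophage markers were above the cardiomyocyte level: 21 of 24 were higher and 0 lower (22 and 0 adjusted over the list alone, camera adjusted p = 5.88e-19), with Ctss at 4.03 ± 0.12. Inflammatory genes moved with them: 11 of 16 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 5.52e-06). For the interferon response 12 of 18 were higher and 0 lower (13 and 0 adjusted over the list alone, camera adjusted p = 7.14e-05, adjusted p = 0.292 with an estimated correlation). For mesothelial genes 10 of 13 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 2.85e-05, adjusted p = 0.116 with an estimated correlation). For proliferation 0 of 25 were higher and 24 lower (1 and 24 adjusted over the list alone, camera adjusted p = 7.91e-12, adjusted p = 0.118 with an estimated correlation). In total 8381 genes were called, 4524 higher and 3857 lower.

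At 4 weeks Myl2 was still 100-fold and Myl3 71.5-fold lower than in cardiomyocytes, and Trim55, a ubiquitin ligase of the sarcomere, 37.8-fold (6.33 ± 0.23 against 11.57 ± 0.13 log2, SD, n = 3). The matrix genes Aspn (-6.27 ± 0.14 SE), Dpt (-6.08 ± 0.19) and Postn (-5.15 ± 0.30) were lower than in the cardiomyocyte arrays, which held matrix transcripts too. Myh6 lay -1.07 ± 0.21, Ryr2 -0.55 ± 0.10 and Pln -2.88 ± 0.25 from the cardiomyocyte level, and Myl7 was within its error of it (0.07 ± 0.16, adjusted p = 0.793). Saa3 (72.6-fold), Scg2 (5.34 ± 0.22), Anxa8 (5.20 ± 0.16), Upk1b (5.03 ± 0.25), Lyz2 (4.98 ± 0.10) and Tspan8 (4.88 ± 0.25) stayed higher. Of sarcomere genes 1 of 32 were higher and 23 lower (the same counts adjusted over the list alone, camera adjusted p = 1.37e-12). Of energy metabolism genes 0 of 31 were higher and 29 lower (the same counts adjusted over the list alone, camera adjusted p = 1.04e-25). Of calcium handling genes 3 of 29 were higher and 19 lower (3 and 21 adjusted over the list alone, camera adjusted p = 3.33e-09). Of other cardiac transcription factors 1 of 16 were higher and 11 lower (1 and 12 adjusted over the list alone, camera adjusted p = 9.74e-09). For ventricular-enriched genes 0 of 6 were higher and 6 lower (the same counts adjusted over the list alone, camera adjusted p = 6.59e-12). For atrial-enriched genes 1 of 9 were higher and 6 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.0686 with an estimated correlation). Macrophage markers stayed above it: 20 of 24 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 1.88e-19). Inflammatory genes lay beside them: 8 of 16 were higher and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 0.000218). Endothelial markers were lower than in the cardiomyocyte arrays, which held endothelial transcripts: 2 of 18 were higher and 14 lower (2 and 15 adjusted over the list alone, camera adjusted p = 5.09e-07). Of cell cycle inhibitors and p53 targets 7 of 11 were higher and 3 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0265, adjusted p = 0.37 with an estimated correlation), with the p53 target Trp53inp1 at 2.44 ± 0.14. Of proliferation genes 0 of 25 were higher and 24 lower (the same counts adjusted over the list alone, camera adjusted p = 3.55e-19). In total 6989 genes were called, 3781 higher and 3208 lower.

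The position between the end points was read on genes with at least a 4-fold difference between cardiomyocytes and fibroblasts. On the 298 cardiomyocyte-high genes the median position of GFP+ cells was 21.3% ± 3.05 (SD, n = 3) at 2 weeks and 34.6% ± 3.89 at 4 weeks, against 3.02% ± 0.966 and 2.77% ± 0.37 in GFP- cells. On the 448 fibroblast-high genes it was 52.4% ± 3.93 and 62.5% ± 2.15 in GFP+ cells, against -3.55% ± 1.49 and -4.58% ± 0.703 in GFP- cells. For gene lists, the position was read on the members called between cardiomyocytes and fibroblasts with at least a 2-fold difference, and the lists lay far apart. Sarcomere genes (29 members) stood at 63.2% ± 8.87 and 74.1% ± 5.22 in GFP+ cells at 2 and 4 weeks, calcium handling genes (20) at 39.8% ± 10.1 and 58.5% ± 5.65, and energy metabolism genes (29) at 19.2% ± 2.74 and 28.6% ± 3.91. Other cardiac transcription factors (7) stood at 14.1% ± 2.5 and 13.1% ± 0.757, atrial-enriched genes (8) at 58.7% ± 1.71 and 70.2% ± 7.91, and ventricular-enriched genes (6) at 6.14% ± 1.47 and 8.72% ± 2.67. The fibroblast-high genes held 21 of the 24 macrophage markers, which stood at 42.6% ± 3.75 and 55.2% ± 1.83, and only 5 of the 33 matrix genes, so the position near 0 of GFP- cells does not describe the matrix. On 16 matrix genes GFP- cells stood at 86.5% ± 16.3 and 81.3% ± 2.27 at 2 and 4 weeks, and GFP+ cells at 38.8% ± 7.98 and 83.7% ± 3.23. On 5 endothelial genes GFP- cells stood at 51% ± 4.71 and 98.2% ± 7.15, and GFP+ cells at 4.67% ± 3.73 and 17.6% ± 2.33. The cardiomyocyte arrays held matrix and endothelial transcripts themselves, so positions on these genes are no measure of cardiomyocyte identity.

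Each difference between GFP+ and GFP- cells, and between 4 and 2 weeks in GFP+ cells, separated all arrays and gave an exact permutation p of 0.1, the smallest that 3 against 3 arrays allow (adjusted p = 0.133 over 8 tests). GFP- cells did not separate by time (exact permutation p = 0.9 on cardiomyocyte-high and 0.4 on fibroblast-high genes). In simulated arrays without change, the position averaged 0.311% on cardiomyocyte-high and 0.279% on fibroblast-high genes. Their noise was independent between genes, so they do not show how far an unchanged group can lie from 0. The fibroblast arrays themselves ran from -1.29% to 1.62% and from -2.12% to 2.18% on these genes. With a slope through 0 in place of the median, GFP+ cells stood at 39.7% and 48.8% on cardiomyocyte-high genes, and the GFP- values on fibroblast-high genes turned positive (2.62% and 0.073%). On genes with a log2 difference of at least 3, the GFP- values on cardiomyocyte-high genes were 5.42% and 4.43%.

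**Figure D2:**
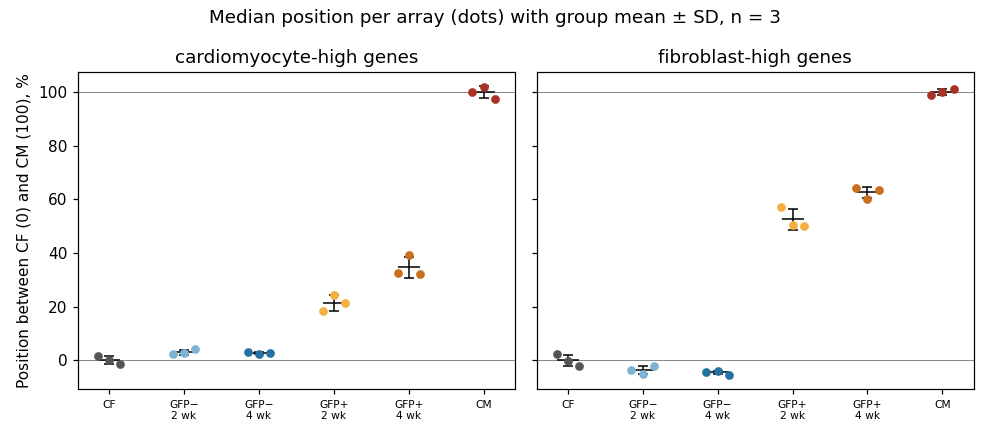
Median position between the fibroblast mean (0%) and the cardiomyocyte mean (100%) per array (dots), with group mean ± SD (n = 3), for 298 cardiomyocyte-high genes and 448 fibroblast-high genes. GFP+ arrays lay between the end points and higher at 4 than at 2 weeks, while GFP- arrays lay near 0 on these genes, which hold 21 macrophage markers and 5 matrix genes on the fibroblast side.

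GFP- cells at 2 weeks were compared with fibroblasts to see what the culture and the attempt at reprogramming left behind. Dpt was 19.5-fold lower (7.57 ± 0.15 against 11.86 ± 0.23 log2, SD, n = 3), and Plac8 (-3.99 ± 0.22 SE), Mmp3 (-3.44 ± 0.18), Medag (-3.00 ± 0.16), chemerin (Rarres2, -3.00 ± 0.11) and the matrix protease Adamts5 (-2.95 ± 0.22) were lower. Cd24a (3.42 ± 0.14), Cd36 (3.15 ± 0.16), Emcn (3.10 ± 0.16), the histidine-degrading enzyme Hal (2.81 ± 0.09) and the light chain Myl4 (2.70 ± 0.25) were higher. Tbx5 was 5.86-fold and Actc1 4.09-fold higher than in fibroblasts, and of the 3 reprogramming factors 2 of 3 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.00362). Gata4 (0.36 ± 0.13) lost its call in 3 of the 6 fits that left out 1 of its arrays. It also lost the call with quantile normalization (adjusted p = 0.0923), with cyclic loess (0.0646) and when only these groups were fitted (0.14).

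Of the matrix genes 1 of 33 were higher and 25 lower (1 and 28 adjusted over the list alone, camera adjusted p = 8.93e-30), with Postn at -2.18 ± 0.30. Of smooth muscle and myofibroblast genes 0 of 15 were higher and 9 lower (0 and 10 adjusted over the list alone, camera adjusted p = 8.76e-10, adjusted p = 0.0509 with an estimated correlation). Of sarcomere genes 12 of 32 were higher and 4 lower (13 and 4 adjusted over the list alone, camera adjusted p = 0.00667, adjusted p = 0.393 with an estimated correlation). Of energy metabolism genes 10 of 31 were higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 0.00844, adjusted p = 0.278 with an estimated correlation). Proliferation genes were higher: 22 of 25 were higher and 0 lower (23 and 0 adjusted over the list alone, camera adjusted p = 3.99e-11, adjusted p = 0.13 with an estimated correlation), with the cell cycle factor Foxm1 at 1.14 ± 0.15. Endothelial markers were higher: 11 of 18 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 1.78e-05, adjusted p = 0.0577 with an estimated correlation), with Cdh5 at 1.97 ± 0.12. Macrophage markers were higher in part: 8 of 24 were higher and 0 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.0269, adjusted p = 0.503 with an estimated correlation). Their list mean was 11.2 ± 0.04 log2 (SD, n = 3). Interferon genes moved beside them: 9 of 18 were higher and 0 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.0153, adjusted p = 0.575 with an estimated correlation). Other cardiac transcription factors were lower on balance: 1 of 16 were higher and 4 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0374, adjusted p = 0.163 with an estimated correlation), with Tbx20 at -1.63 ± 0.15. For atrial-enriched genes 3 of 9 were higher and 1 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0312, adjusted p = 0.191 with an estimated correlation). In total 4520 genes were called, 2742 higher and 1778 lower (60.7% higher, 53.9% after cyclic loess). The lean was the opposite among the 472 that differed at least 2-fold, with 130 higher and 342 lower. With array weights the count was 7398.

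At 4 weeks the largest rises in GFP- cells over fibroblasts included endothelial genes. Emcn was at least 33.6-fold (11.06 ± 0.15 against 5.99 ± 0.39 log2, SD, n = 3), Cdh5 12.5-fold and Cd36 25.3-fold higher. Cd24a (4.06 ± 0.14 SE) and Mest (3.74 ± 0.16) were higher. Dpt (-4.59 ± 0.19), Plac8 (-4.08 ± 0.22), Adamts5 (-3.03 ± 0.22), Aspn (-3.00 ± 0.14), Tmem92 (-2.99 ± 0.27) and Fndc1 (-2.96 ± 0.18) were lower. Of endothelial markers 12 of 18 were higher and 0 lower (13 and 1 adjusted over the list alone, camera adjusted p = 2.12e-14), with Pecam1 at 2.89 ± 0.14. For adipocyte genes 3 of 9 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0145, adjusted p = 0.295 with an estimated correlation), with the fatty acid binding protein Fabp4 at 1.83 ± 0.11 and the transcription factor Pparg at 1.35 ± 0.19. Matrix genes were lower: 1 of 33 were higher and 25 lower (1 and 28 adjusted over the list alone, camera adjusted p = 5.09e-31). Smooth muscle and myofibroblast genes were lower too: 0 of 15 were higher and 12 lower (0 and 13 adjusted over the list alone, camera adjusted p = 1.18e-14), with Acta2 at -1.94 ± 0.23. Of the macrophage markers 5 of 24 were higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.0133, adjusted p = 0.435 with an estimated correlation), with Cx3cr1 lower (-1.01 ± 0.13). Inflammatory genes were higher on balance: 5 of 16 were higher and 2 lower (6 and 2 adjusted over the list alone, camera adjusted p = 0.00747), with lipocalin 2 (Lcn2) at 3.15 ± 0.18 and the chemokine Ccl5 at 2.64 ± 0.32. Interferon genes were higher as well: 10 of 18 were higher and 0 lower (13 and 0 adjusted over the list alone, camera adjusted p = 3.88e-10, adjusted p = 0.096 with an estimated correlation). Of immediate early genes 6 of 13 were higher and 0 lower (the same counts adjusted over the list alone, camera adjusted p = 0.00475, adjusted p = 0.313 with an estimated correlation). Of sarcomere genes 10 of 32 were higher and 4 lower (11 and 5 adjusted over the list alone, camera adjusted p = 0.00598, adjusted p = 0.385 with an estimated correlation). Of the reprogramming factors 2 of 3 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 7.11e-05), with Tbx5 at 1.90 ± 0.11. Proliferation genes were lower: 0 of 25 were higher and 16 lower (1 and 20 adjusted over the list alone, camera adjusted p = 6.96e-11, adjusted p = 0.135 with an estimated correlation). In total 2286 genes were called, 1152 higher and 1134 lower, and 3720 with array weights. At least 2-fold, 176 were higher and 226 lower.

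Within GFP- cells, Lum rose 9.93-fold from 2 to 4 weeks (6.85 ± 0.23 to 10.16 ± 0.16 log2, SD, n = 3) and Lcn2 7.44-fold. Cd209f (3.06 ± 0.30 SE), Ms4a4a (2.84 ± 0.15) and the complement receptor Vsig4 (2.60 ± 0.15), genes of macrophages, and Cd55 (2.58 ± 0.20) rose. Hal (-2.21 ± 0.09), Ifitm6 (-2.15 ± 0.18), Clec4e (-2.14 ± 0.17), Gpr84 (-2.07 ± 0.16), Bub1 (-1.95 ± 0.19) and Mboat1 (-1.84 ± 0.14) fell. Proliferation genes fell together: 0 of 25 rose and 24 fell (the same counts adjusted over the list alone, camera adjusted p = 2.44e-26), with Mki67 at -1.67 ± 0.16. Endothelial markers rose: 7 of 18 rose and 1 fell (7 and 2 adjusted over the list alone, camera adjusted p = 5.63e-05, adjusted p = 0.0725 with an estimated correlation), with Emcn at 1.97 ± 0.16 and Pecam1 at 1.69 ± 0.14, while Vwf, singled out after its value was seen, fell by 0.85 ± 0.10. Macrophage markers did not move as a list: 0 of 24 rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.875). For the interferon response 2 of 18 rose and 0 fell (the same counts adjusted over the list alone, camera adjusted p = 0.00223, adjusted p = 0.435 with an estimated correlation). For other cardiac transcription factors 5 of 16 rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0401, adjusted p = 0.168 with an estimated correlation), with Tbx20 at 1.40 ± 0.15. For sarcomere genes 1 of 32 rose and 1 fell (the same counts adjusted over the list alone, camera adjusted p = 0.567). In total 3465 genes were called, 1426 higher and 2039 lower (41.2% higher), and 6087 with array weights. At least 2-fold, 162 were higher and 146 lower. After cyclic loess normalization 2090 were higher and 1775 lower (54.1% higher), so the split between rises and falls depended on the scaling.

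**Figure D3:**
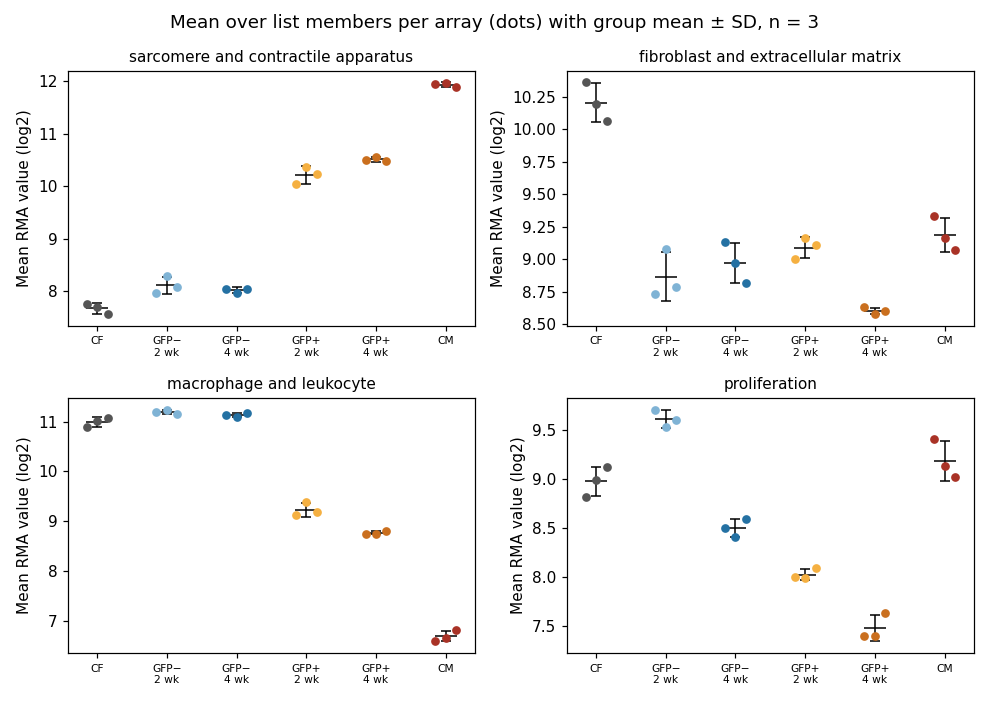
Mean log2 RMA value over the members of 4 gene lists per array (dots), with group mean ± SD (n = 3), in the 6 groups. In GFP+ cells the sarcomere mean rose from 10.21 to 10.51 between 2 and 4 weeks, the macrophage mean fell from 9.23 to 8.77 and lay between the cardiomyocyte and GFP- levels, and the proliferation mean fell from 8.03 to 7.48.

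The interaction asked which genes changed differently over time in GFP+ and in GFP- cells. Ppp1r3a rose by 2.06 ± 0.16 log2 (SE, n = 3 arrays per group) in GFP+ cells and changed by -0.19 ± 0.16 in GFP- cells, a difference of 2.25 ± 0.22. Nebl (2.21 ± 0.15), Rgs7 (1.99 ± 0.24), Pln (1.77 ± 0.35) and Mlf1 (1.74 ± 0.17) also changed more positively in GFP+ cells, as did Gpr84 (1.79 ± 0.22), which fell by 2.07 ± 0.16 in GFP- cells. Vsig4 (-2.68 ± 0.21), Cd209f (-2.56 ± 0.43), Lcn2 (-2.45 ± 0.26), Bex1 (-2.16 ± 0.27), the kinase Bmx (-2.13 ± 0.32) and the cytokine Il6 (-2.13 ± 0.27) changed more positively in GFP- cells. Among interaction terms of sarcomere genes 7 of 32 were positive and 0 negative (12 and 0 adjusted over the list alone, camera adjusted p = 5.09e-07, adjusted p = 0.107 with an estimated correlation), with Actn2 at 1.18 ± 0.17. For calcium handling genes 4 of 29 were positive and 0 negative (9 and 0 adjusted over the list alone, camera adjusted p = 7.23e-05, adjusted p = 0.106 with an estimated correlation). For energy metabolism genes 7 of 31 were positive and 1 negative (13 and 1 adjusted over the list alone, camera adjusted p = 1.5e-06, adjusted p = 0.0532 with an estimated correlation). Among matrix genes 0 of 33 were positive and 11 negative (0 and 14 adjusted over the list alone, camera adjusted p = 8.74e-13, adjusted p = 0.087 with an estimated correlation), with Fn1 at -1.13 ± 0.22. Macrophage markers gave a negative shift: 1 of 24 were positive and 4 negative (1 and 12 adjusted over the list alone, camera adjusted p = 1.94e-10). Inflammatory genes moved with them: 0 of 16 were positive and 7 negative (1 and 10 adjusted over the list alone, camera adjusted p = 8.94e-12). For proliferation 7 of 25 were positive and 0 negative (20 and 0 adjusted over the list alone, camera adjusted p = 2.17e-12, adjusted p = 0.11 with an estimated correlation). For endothelial markers 2 of 18 were positive and 6 negative (2 and 8 adjusted over the list alone, camera adjusted p = 3.3e-05, adjusted p = 0.0669 with an estimated correlation). In total 785 genes were called, 370 positive and 415 negative. The balance of signs turned with the scaling, with 378 positive and 638 negative after cyclic loess and 653 and 451 with the spread covariate. The count was 514 without replicate 1 of the 4-week GFP- cells and 4191 with array weights, and other splits of the arrays gave counts as large.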

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

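The tests of explanations given in this part were chosen after the results had been seen, and the exchanges of arrays between groups were chosen before. Splits here are regroupings of the arrays into groups of the same size.

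The interaction of cell type and time differed between groups in 785 genes. Splits that exchange 2-week and 4-week labels within each cell type were drawn at random, and 7 of 100, the real one among them, called at least as many genes as the 664 called with these 4 groups alone. The highest other split among those drawn called 1603. Of the 6 other splits as large, 5 gave all 6 GFP- arrays the other time and also relabelled 2 GFP+ arrays. The exchange of all GFP- labels alone was not among the splits drawn and called 4468, several times the real count. By construction, exchanging all GFP- labels adds the changes over time of the 2 cell types where the interaction subtracts them. Most of the splits as large are therefore not free of real change, so these splits do not exclude chance and give no verdict on it. For each of the 11 comparisons of 2 groups, only the real split (1 of 10) called as many genes as observed, and the highest other split called 0 genes. With so few splits the share cannot fall under 0.05.

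Among single genes, the interaction was positive for Ppp1r3a (2.25 log2), Nebl (2.21), Rgs7 (1.99), Gpr84 (1.79), Pln (1.77) and Mlf1 (1.74). It was negative for Vsig4 (-2.68), Cd209f (-2.56), Lcn2 (-2.45), Bex1 (-2.16), Bmx (-2.13) and Il6 (-2.13). Among gene lists, the median interaction was 0.26 for sarcomere genes, 0.2 for calcium handling and ion channels, 0.35 for muscle energy metabolism, 0.16 for skeletal muscle and 0.57 for proliferation. The median was -0.48 for fibroblast and matrix genes, -0.22 for endothelial, -0.47 for macrophage, -0.45 for interferon, -0.83 for inflammatory and -0.31 for immediate early genes.

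Probe sets that name no single gene were left out of the comparisons, and 99 of these 6927 were at least 2-fold higher in 4-week GFP+ cells than in fibroblasts.

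Macrophage transcripts in GFP+ arrays lay between the cardiomyocyte and the GFP- levels. Macrophages carried over from the GFP- cells would give every marker the same linear share of the GFP- signal, for which the ratio of the 75th to the 25th percentile had to be 2 or less. The ratio was 1.68 at 2 weeks and 1.67 at 4 weeks over 24 markers, with median shares of 16.7% and 11.2%, so carry-over remains a candidate explanation for the middle of the markers. Lyz2 (46.8% and 33.9%), Tyrobp (38.5% and 28.5%), Ctss (34.2% and 23.3%) and Mpeg1 (32.1% and 19%) had higher shares than the middle of the markers, C1qa (11.1% and 7.95%), Fcgr3 (12.3% and 8.16%), Itgam (13.2% and 8.14%), Adgre1 (12.8% and 11.5%) and Coro1a (14.7% and 4.53%) were on the low side at 1 or both times, and H2-Ab1 (99.2% and 49.8%), H2-Aa (119% and -7.16%) and Cd74 (0.69% and 45%) had GFP- levels of 5.58 to 6.77 log2, near background. Compression of bright signals, which would raise the share of the brightest markers, gave Spearman correlations of 0.18 and 0.32 with the GFP- level, and this is left open.

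Endothelial transcripts rose in GFP- arrays from 2 to 4 weeks. A larger number of unchanged endothelial cells would raise all markers that lay above the fibroblast level by 1 factor. Over 11 such markers the factor had a median of 1.96 and a ratio of the 75th to the 25th percentile of 3.14, with 5 markers risen and Vwf fallen. Some of the 11 lay little above fibroblasts at 2 weeks (Tie1 by 0.31 and Esam by 0.36 log2), where the factor is poorly measured. The ratio by itself therefore does not decide on that explanation. Of the markers furthest above, Emcn, Cdh5 and Pecam1 rose by 1.97, 1.68 and 1.69 log2, while Vwf fell by 0.85. Array scaling was tested with quantile and cyclic loess normalization, and 7 of 7 risen markers stayed higher with both, which speaks against scaling. A change in the state of the cells was not tested.

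Deviations of arrays from their group means shared 1 axis, which held 28.7% of the remaining variance. The axis followed the spread of the values on each array (r = 0.96 over 18 arrays, permutation p = 0.00042, and 0.95 without the 2 farthest arrays). Quantile normalization, which gives every array the same spread, left 21.2% on the axis and cyclic loess 22.2%, so a technical and a biological origin cannot be told apart.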

How the results depend on the processing

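The alternatives were chosen before the data were examined, except the array spread as a covariate, which was chosen after the results had been seen. Where a value moved, the cause was not tested unless stated.

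All counts of called genes kept within 1.5-fold with all probe sets, an intensity trend, quantile or cyclic loess normalization, and without genes under the 25th percentile. With the replicate block, the count of iCM_4wk vs iCM_2wk was 2420 against 2297. A change of at least 1 log2 lowers every count by construction. It left 2348 (CM vs CF), 1440 (iCM_2wk vs CF), 1541 (iCM_4wk vs CF), 1798 (iCM_2wk vs GFPneg_2wk), 1703 (iCM_4wk vs GFPneg_4wk), 101 (iCM_4wk vs iCM_2wk), 308 (GFPneg_4wk vs GFPneg_2wk), 2090 (iCM_2wk vs CM), 1660 (iCM_4wk vs CM), 472 (GFPneg_2wk vs CF), 402 (GFPneg_4wk vs CF) and 222 genes (interaction). The overlap between times became 546 for higher and 768 for lower genes.

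Array weights raised the count to 5985 (iCM_4wk vs iCM_2wk), 6087 (GFPneg_4wk vs GFPneg_2wk), 7398 (GFPneg_2wk vs CF), 3720 (GFPneg_4wk vs CF) and 4191 (interaction). The share of higher genes also crossed 50% in iCM_4wk vs CF (48.5%, 52% with quantile normalization), iCM_2wk vs GFPneg_2wk (46.8%, 50.9% with quantile normalization), iCM_4wk vs GFPneg_4wk (50.2%, 45.8% with cyclic loess) and GFPneg_4wk vs CF (50.4%, 46% with the array spread as a covariate). For iCM_4wk vs iCM_2wk the array spread as a covariate gave 3626, and only the groups compared gave 1486. Leaving out 1 array, which leaves fewer samples, gave 1289 to 1958 there and 514 to 1004 for the interaction.

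Position changed with the genes and the summary used. For cardiomyocyte-high genes, a log2 difference of at least 3 gave 28.6% (iCM_2wk), 49.2% (iCM_4wk), 5.42% (GFPneg_2wk) and 4.43% (GFPneg_4wk), and at least 1 gave 1.67% for GFPneg_4wk. A slope through 0 gave 39.7%, 48.8%, 8.15% and 9.64% in the same order. Cyclic loess gave 1.74% (GFPneg_2wk) and 3.22% (GFPneg_4wk), quantile normalization 3.5% (GFPneg_4wk), and leaving out 1 array 2.31% to 3.28% (GFPneg_4wk).

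For fibroblast-high genes, at least 1 log2 gave 47.8% (iCM_2wk) and 57.7% (iCM_4wk), and at least 3 gave 59.4% (iCM_4wk) and -3.44% (GFPneg_4wk). The slope gave 47% and 56.5% for GFP+ cells and reversed the GFP- values to 2.62% (GFPneg_2wk) and 0.073% (GFPneg_4wk). Leaving out 1 array gave -5.31% to -4.07% (GFPneg_4wk).

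Of the 149 tests of a list in a comparison that passed, 79 lost the call with an estimated correlation, 8 with cyclic loess, 5 with fry and 11 without the dimmest genes, and all kept it with the replicate block. None of the genes with the largest changes and none of the anchor genes reversed. List members named only as such were not run under the alternatives. Genes near background limit what falls can be seen.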

Other observations

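The tests and gene choices in this part were made after the results had been seen.

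Atrial-enriched genes lay closer to the cardiomyocyte level than ventricular-enriched genes in GFP+ cells at 4 weeks. On members with at least a 2-fold difference between cardiomyocytes and fibroblasts, the mean position was 64.8% over 8 atrial genes and 7.51% over 6 ventricular genes, a difference of 57.3 points. Regrouping the genes gave an exact permutation p of 0.017 (3003 regroupings). This test was written after the difference had been seen and used the same genes and arrays, so it describes the gap between the lists and is no evidence for an atrial programme of the cells. Sln (131%), Myl4 (110%), Myl7 (101%), Nppa (74.2%) and Kcnj3 (66.2%) stood high among the atrial genes, and Kcna5 (26.2%) and Gja5 (11%) did not. Of the ventricular genes, Myh7 stood at 17.7%, Myl3 at 2.65%, Irx4 at 0.902% and Myl2 at -5.13%. Bmp10, Hey2 and Kcnip2 had fibroblast means under 6.16 log2, which are not above background, so their own positions are not given, although both list means include them.

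Some genes left the axis between the end points. In 4-week GFP+ cells, 208 genes were called and at least 2-fold higher than in fibroblasts, in cardiomyocytes and in 4-week GFP- cells, against 1 if the calls were independent, and 104 were lower in the same sense, against 2. The comparisons share the GFP+ arrays, so independence is a low bar. The fast skeletal troponin Tnnt3 was higher by 3.8, 3.45 and 3.91 log2 against the 3 groups in that order, parvalbumin (Pvalb) by 3.75, 3.98 and 3.44, and Enpep by 5.76, 2.97 and 5.08. Scg2 was higher by 4.68, 5.34 and 2.88, Anxa8 by 4.92, 5.2 and 2.71, the mast cell protease gene Mcpt4 by 4.18, 4.22 and 3.06, and Mlana by 4.54, 2.47 and 3.21. Among the lower genes were Lum, Etv1, Rasgrp3 and the cell cycle genes Top2a, Cdk1, Bub1 and Mki67.

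Probe sets of 1 gene did not always move together. For Trdn in 2-week GFP+ cells against fibroblasts, the probe set used gave 1.5 log2 and the others -1.48 and -1.18, and for Top2a in 2-week GFP- cells against fibroblasts the probe set used gave 0.6 and the other -1.04.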
